A study of Mus musculus with 2 samples.

How the data were processed

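Chromatin accessibility was measured by DNase-seq in lung tissue of female B6CASTF1/J mice aged 36 days. The labels give 1 group with 2 biological replicates, from the animals numbered 6 (replicate 1) and 5 (replicate 2), and both animals carry one donor identifier. Whether they were littermates is not given in the sources used here.

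For each replicate the authors deposited 2 lists of peaks, a list of footprints and a list of false discovery rates, all on the mm10 build per the file headers and labels. Each list was made from that replicate's own filtered alignments, so peaks were called per animal and not on pooled reads. The aligner, the callers and their versions are not given in the sources used here. The peak lists give a signal value per peak that the authors deposited without a stated scale. In both replicates 100% of these values were whole multiples of a fixed step, to within 0.05 steps, which is how a density of cuts scaled to depth behaves. The step of replicate 2 was 1.41 times that of replicate 1, so if a step stands for 1 cut, replicate 1 held 1.41 times as many cuts. The p-value column of the deposited peak lists was empty, so the threshold of each list was read from the false discovery rates (FDR) that the authors deposited per interval. Every peak of the longer list held a base at or under FDR 0.05, and every peak of the shorter list held a base at or under FDR 0.001. The longer list was used throughout and the shorter as an alternative. In the deposited footprint lists every line carries the same value, 0.01, so only the intervals were used. Further files named in the labels were not used here.

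These steps bear on the measurements in 4 ways. The number of peaks, their shares between replicates and the number of footprints can move with depth. Reads of a hybrid animal aligned to the C57BL/6J reference can be lost where the other parent's sequence differs from it. DNase I prefers some sequences over others, and whether the footprint calls were corrected for this is not given. A peak in a tissue sample does not say which of its cells carried it.

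Gene models came from GENCODE M21 on GRCm38.p6, the same chromosomes as mm10; 0 peaks lay past a chromosome end. Coordinates are given 1-based. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 for sequence scans, bedtools 2.31.1 and matplotlib 3.10.9.

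Peaks were shared when they overlapped a peak of the other replicate by 1 bp or more, and the Jaccard index was taken over bases. Both were set against 100 shuffles of the replicate's own peaks within chromosomes, outside gaps, with the other replicate's peaks left in place. A peak's class was that of its centre, in the order promoter (1000 bp either side of a transcription start of a protein-coding gene), exon, intron and intergenic. Fold values are over the share of the genome's bases in the class.

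A gene's promoter counted as accessible where a peak overlapped the window of 1000 bp either side of any of its annotated starts, and the tests used promoters with a peak in both replicates. Each of 37 gene lists was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 37 lists. A list was called at an adjusted p under 0.05. Promoters rich in CpG are accessible in most tissues, so each list was also compared with 10000 random lists matched on promoter CpG content (200 candidate genes per member), with the same adjustment. For the locus, peaks in the gene body and 10000 bp either side were counted per 10 kb, averaged over replicates, and the list's median was placed among 10000 random lists matched on locus length and promoter CpG content. The smallest two-sided p this allows is 0.0002. Both tests run over genes within these libraries and say nothing of the spread between animals; with 1 group of 2 animals no comparison between conditions was possible. The lists held markers of lung cell types, blood cells and other tissues, transcription factors of lung epithelium and mesenchyme, housekeeping, clock, immediate early and interferon genes, 2 Hox groups, and genes of X inactivation and escape; members of the last list that are not protein-coding were left out of the tests.

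Windows of 200 bp centred on peaks were searched on both strands for 37 consensus sequences. The background was windows of the same length centred 1500 bp from the peak centre that overlapped no peak. Each consensus was also searched as 5 seeded shuffles of its letters. For footprints, the interval with 5 bp either side was searched and compared with windows of the same lengths placed at random inside the same animal's peaks and outside footprints. These windows were drawn from all peaks in proportion to width, not from the peak that held the footprint. Density by chromosome was peaks per Mb of sequenced bases.

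Genes named by value were chosen by rule: from each list the 3 members with the strongest promoter peaks, up to 2 with no promoter peak in either replicate and up to 2 with a peak in 1 replicate, and all members of lists of 7 or fewer. To these the rule added the 10 loci of 30000 bp or more with most peaks per 10 kb, the 5 longest regions under FDR 0.05 of each replicate, and the 8 highest and 3 lowest consensus sequences. The values of some genes that the rule names are not reported. The gene lists, consensus sequences, tests, this rule and the alternatives were fixed before the data were examined, except the alternative with the authors' FDR 0.001 lists. Merged regions under FDR 0.05 stood in for hotspots, which were planned but not used here. The other alternatives were a reciprocal overlap of 50%, equal numbers of peaks, FDR 0.005, promoter windows of 500 and 2500 bp, the strongest 50% of each list, locus flanks of 0 and 50000 bp, peaks outside promoters, a GC-matched background, footprint flanks of 0 and 10 bp, and each replicate alone.

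The methods were tested on simulated data. Simulated overlaps came back without error. Among simulated lists of 12 genes, the promoter test called 91.3% of lists with all promoters accessible, 90.0% of lists with 15% accessible, and 1.19% of unchanged lists. Unchanged lists of CpG-poor genes had a Fisher's exact p under 0.05 in 85% of cases and a CpG-matched p under 0.05 in 1%, so the matched result stands beside each call. The locus test gave p under 0.05 for 83.8% of lists at 2.2 times the density and for 3.75% of unchanged lists.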

Results

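DNase-seq mapped accessible chromatin in the lung of female B6CASTF1/J mice, the F1 offspring of C57BL/6J and CAST/EiJ parents, at 36 days of age. DNase I cuts nuclear DNA most readily where nucleosomes are displaced, so clusters of cuts, called here peaks, lie over active promoters, enhancers and insulators. Short protected stretches within them, called footprints, lie where a protein covers the DNA. The series held 1 group of 2 animals and no other condition, so the data show which sites were accessible in this tissue and how far both animals gave the same sites. Replicate 1 had 217801 peaks covering 40.1 Mb (1.52% of the genome) and replicate 2 had 161754 peaks covering 30.7 Mb (1.16%), with median widths of 180 and 190 bp. If a step of the peak values stands for 1 cut, replicate 1 held 1.41 times as many cuts as replicate 2. The value given for a peak is the authors' own; its median was 0.634 in replicate 1 and 0.738 in replicate 2, and its largest was 82.3 and 70.

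Most sites of the animal with fewer peaks were also sites of the other. Of the replicate 2 peaks, 90.2% overlapped a replicate 1 peak, and of the replicate 1 peaks, 67.2% overlapped a replicate 2 peak. Shuffled peaks overlapped in 3.27% and 2.43%. Over bases, the Jaccard index was 54.8%, against 0.717% and 0.720% after shuffling the peaks of replicates 1 and 2. Strong peaks were shared almost without exception: 99.4% of the strongest 10% of replicate 1 and 99.8% of that of replicate 2 were shared, against 16.9% and 55.6% of the weakest 10%. Promoter peaks were shared more often (77.5% in replicate 1 and 92.1% in replicate 2) than intergenic peaks (64.9% and 88.9%). Promoter peaks were also stronger, and the classes were not compared at like strength. With the same number of strongest peaks from each animal the shares were 80.9% and 80.8%.

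**Figure D1:**
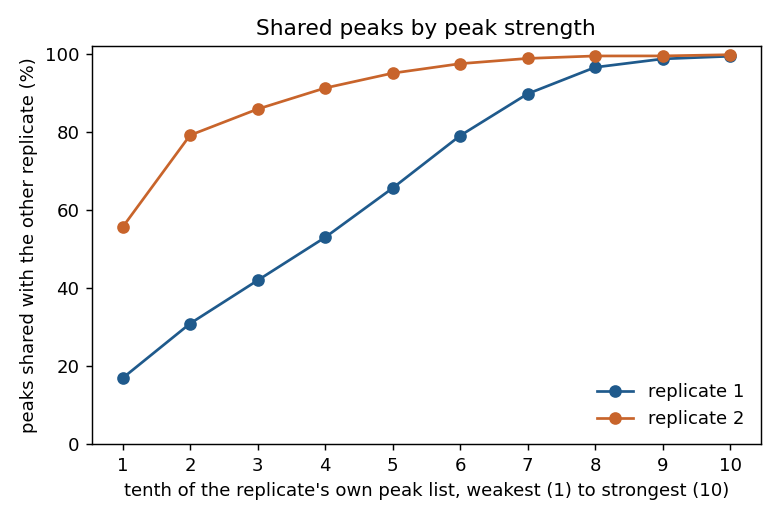
Percent of peaks that overlap a peak of the other replicate by 1 bp or more, for each 10% of a replicate's own list from the weakest (1) to the strongest (10); a line stands for each replicate. In replicate 1 the share runs from 16.9% to 99.4%, and in replicate 2 from 55.6% to 99.8%.

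Promoters held far more of the peaks than their length accounts for. Of all peaks, 20% ± 1.70 (SD, n = 2) were centred within 1000 bp of a protein-coding transcription start, 5.42 ± 0.460 times the share of the genome in that class. Exons outside promoters held 3.76% ± 0.0122 (1.42 times their share), introns 37.6% ± 1.15 (1.12 times) and intergenic sequence 38.6% ± 0.538 (0.642 times). Most peaks thus lay in introns or between genes. Promoter peaks were also stronger, with median values of 1.16 and 1.56 in replicates 1 and 2 against 0.544 and 0.627 for intergenic peaks. The promoter share depended on the window and on strength: it was 14.8% with 500 bp, 27.6% with 2500 bp and 27.7% among the strongest 50% of peaks.

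At single genes, 15291 of 21911 protein-coding promoters (69.8%) held a peak in both animals, 604 in replicate 1 alone and 187 in replicate 2 alone. Promoters of lung epithelial genes were accessible without exception in several lists. All 14 alveolar type 2 genes had a promoter peak in both animals, among them those of the surfactant proteins. This list exceeded other genes (adjusted p = 0.0305, two-sided Fisher's exact test) and exceeded lists of like CpG content, whose median was 50% (adjusted p = 0.00247). Its strongest promoters were Etv5, a transcription factor of type 2 cells (22.3 in replicate 1 and 29.4 in replicate 2; peak at chromosome 16, 22439681 to 22439920, mm10), the lipid transporter Abca3 (11.1 and 16.1; chromosome 17, 24351821 to 24352080) and the mucin Muc1 (9.37 and 8.24). All 12 club and secretory cell genes likewise had a promoter peak in both animals (adjusted p = 0.0478 by Fisher's exact test and 0.00247 against CpG-matched lists, whose median was 41.7%), led by Cbr2 (4.06 and 3.23), Hp (2.85 and 2.98) and Upk3a (2.49 and 2.39). So did all 13 alveolar type 1 genes (adjusted exact p = 0.0358), led by Vegfa (9.82 and 9.08), Hopx (7.08 and 5.62) and Rtkn2 (7.30 and 4.50). All 16 lung epithelial transcription factors did too (adjusted exact p = 0.0223), led by Id2 (21.7 and 21.1), Klf5 (9.98 and 14.8) and Cebpa (10.6 and 10.3). For the latter 2 lists the CpG-matched medians were 84.6% and 87.5% (adjusted permutation p = 0.248 and 0.364). At 100% neither list could go higher, so that test could not set them apart. Their median promoter values were 3.04 and 5.17, against 4.66 and 5.81 for CpG-matched lists.

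Ciliated, basal and neuroendocrine lists did not pass the test. Of 12 ciliated cell genes 11 had a promoter peak in both animals (adjusted p = 0.180, Fisher's exact test), with Rsph1 (18.6 and 19.2), Tppp3 (16.1 and 19.1) and Dynlrb2 (12.4 and 10.6) strongest and the axonemal dynein Dnah5 without a peak. Of 8 airway basal genes only 3 did (adjusted exact p = 0.105). Aqp3 (1.27 and 2.03), Ngfr (0.751 and 1.21) and Trp63 (0.679 and 0.642) had weak peaks, the keratins Krt14 and Krt15 had none, and Krt5 had one in replicate 2 alone (0.325). Of 7 neuroendocrine genes 6 did (adjusted exact p = 0.765). They were Syp (2.11 and 1.59), Chga (1.77 and 0.968), Resp18 (1.07 and 0.619), Calca (0.763 and 0.278), Uchl1 (0.628 and 0.777) and Insm1 (0.555 and 0.389).

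Endothelial genes were accessible almost throughout: 23 of 24 promoters had a peak in both animals (adjusted p = 0.0223, Fisher's exact test), against 66.7% of CpG-matched genes (adjusted p = 0.00863). Calcrl (9.07 and 6.04), the junction protein Esam (6.75 and 8.53) and the tight-junction claudin Cldn5 (6.51 and 6.02) were strongest, and Emcn had a peak in replicate 2 alone (0.238). Of 7 lymphatic endothelial genes, 3 had one in both animals (adjusted exact p = 0.287): Lyve1 (1.75 and 1.67), Flt4 (2.03 and 1.25) and Prox1 (1.87 and 1.29), with no peak at Ccl21a, Mmrn1, Reln or Stab2. The fibroblast list had 15 of 17 (adjusted exact p = 0.180), led by Eln, the gene of elastin (6.84 and 10), Col1a1 (10.6 and 5.55) and Plin2 (4.63 and 4.37), with no peak at Lum and one in replicate 1 alone at Pi16 (0.757). It exceeded CpG-matched lists, whose median was 58.8% (adjusted permutation p = 0.0259). Smooth muscle and pericyte genes had 12 of 14 (adjusted exact p = 0.334), with Myh11 (3.73 and 3.58), Tagln (4.44 and 2.5) and Des (1.76 and 1.91) strongest, none at Actg2, and Cox4i2 in replicate 1 alone (0.998). Mesenchymal transcription factors had 13 of 14 (adjusted exact p = 0.126), with Tbx3 (11.5 and 10.8), Gli1 (10.4 and 5.17) and Tbx2 (6.01 and 7.45) strongest and Prrx1 in replicate 1 alone (0.258). Mesothelial genes had 4 of 6 (adjusted exact p = 1.00), all weak: Msln (0.594 and 0.666), Wt1 (0.527 and 0.666), Upk1b (0.510 and 0.515) and Muc16 (0.157 and 0.262) in both animals, and Upk3b (0.437) and Lrrn4 (0.398) in replicate 1 alone.

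Among blood cell lists, alveolar macrophage genes had the highest share at FDR 0.05, with 12 of 13 promoters accessible in both animals. The list did not pass Fisher's exact test (adjusted p = 0.180) but exceeded CpG-matched lists, whose median was 46.2% (adjusted p = 0.00370). Bhlhe41 (3.38 and 3.40), Pparg, a nuclear receptor of these cells (2.96 and 2.72), and Cidec (1.56 and 1.25) were strongest, and Ear1 had no peak. The difference from other genes turned from 22.5 percentage points to -24.1 among the strongest 50% of peaks and -12.3 in the FDR 0.001 lists. In the former B cell (-12.5), monocyte (-19.7) and T cell genes (-20.9) ranked above it, and in the latter B cell genes (-6.13). Monocyte and interstitial macrophage genes had 9 of 14 (adjusted exact p = 0.839), with Cd68 (4.23 and 3.41) and Spi1 (4.07 and 3.49) among the strongest. C1qb had none, C1qa had one in replicate 2 alone (0.270) and Cx3cr1 in replicate 1 alone (0.393). Dendritic cell genes had 7 of 10 (adjusted exact p = 1.00), with Irf8 (4.49 and 5.76), Zbtb46 (3.81 and 5.33) and Batf3 (1.16 and 1.24) strongest and none at Xcr1 or Clec9a. Neutrophil genes had 4 of 10 (adjusted exact p = 0.126), with Camp (1.33 and 1.48), S100a8 (1.67 and 0.975) and Ltf (0.404 and 0.404) strongest and none at S100a9 or Csf3r.

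Natural killer and erythroid genes were accessible less often than other genes, while the T and B cell lists did not pass the test. T cell genes had 7 of 12 promoters in both animals (adjusted p = 0.450, Fisher's exact test), with Lck (8.78 and 6.95), Cd2 (2.66 and 2.91) and Tcf7 (1.78 and 2.21) strongest, none at the coreceptors Cd4 and Cd8a, and the receptor chains Cd3e (0.376) and Cd3g (0.404) in replicate 1 alone. In replicate 1 by itself 10 of 12 had a peak (83.3%), above the 72.5% of all protein-coding genes, and in replicate 2 7 had one. B cell genes had 7 of 10 (adjusted exact p = 1.00), with Ebf1 (5.70 and 4.39), Cd22 (5.78 and 1.86) and Pax5 (4.07 and 3.39) strongest and Cd79a (0.701) in replicate 1 alone. For this list replicate 1 had 10 of 10 and replicate 2 had 7. Natural killer genes fell below other genes with 2 of 10 (adjusted exact p = 0.0155), namely Prf1 (0.656 and 0.571) and Klrd1 (0.432 and 0.270), with none at Tbx21 or Gzma. Taken singly, replicate 1 had 5 of 10 and replicate 2 had 3. Erythroid genes also fell below other genes with 3 of 11 (adjusted exact p = 0.0223), among them Epor (2.27 and 2.11) and Ank1 (0.432 and 0.515), with none at the globin genes Hbb-bs and Hba-a1. For this list replicate 1 had 5 of 11 and replicate 2 had 3. Neither stood apart from CpG-matched lists (adjusted permutation p = 0.277 and 0.532).

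Genes of other tissues were below the other protein-coding genes in most lists. By Fisher's exact test, hepatocyte genes had 3 of 15 promoters in both animals (adjusted p = 0.00182), pancreas 2 of 12 (adjusted p = 0.00271). Kidney genes had 4 of 12 and male germ cell and photoreceptor 3 of 10 each (adjusted exact p = 0.0314 in all 3), and intestine 4 of 11 and skeletal muscle 6 of 15 (adjusted exact p = 0.0478 in both). Cardiomyocyte genes, with 6 of 14 (adjusted exact p = 0.0726), and neuronal genes, with 10 of 16 (adjusted exact p = 0.679), did not pass. Promoters without a peak in either animal included Apoa1 and Ttr, secreted by liver, Cpa1 and Pnlip, enzymes of the exocrine pancreas, and Umod and Slc12a1 of the kidney tubule. Others were Prm1 and Prm2, the protamines of sperm, Crx of photoreceptors, Cdx1 and Cdx2 of the intestine, Acta1 and Myh1 of skeletal muscle, Myh6 and Tnnt2 of the heart, and Neurod1 and Neurod6 of neurons. The hepatocyte gene Alb had only a weak peak (0.264 and 0.262). Some listed promoters were strong, among them Myl4 (17.7 and 15) of the heart list, Mylpf (15.7 and 18.9) of the skeletal muscle list, Opn1sw (7.25 and 6.53) of the photoreceptor list, Cela1 (7.27 and 2.67) of the pancreas list and Dazl (5.50 and 8.26) of the germ cell list. Only the pancreas list stayed below CpG-matched lists, whose median was 58.3% (adjusted permutation p = 0.0148). The matched adjusted p was 0.184 for hepatocyte, 0.357 for kidney, 0.0855 for male germ cell, 0.469 for photoreceptor and skeletal muscle and 0.778 for intestine.

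Of 16 Hox genes of paralogue groups 9 to 13, which pattern the posterior body, only 3 had a promoter peak in both animals (adjusted p = 0.00134, Fisher's exact test), while 93.8% of genes of like CpG content did (adjusted p = 0.00247). The 3 were Hoxa10 (3.54 and 1.74), Hoxc10 (1.87 and 0.785) and Hoxc13 (0.550 and 0.460). Hoxa9 and Hoxa11 had none, and Hoxb9 (0.505) and Hoxc9 (0.320) had one in replicate 1 alone. Taken by itself, replicate 1 had 6 of 16 (adjusted exact p = 0.0434) and replicate 2 had 3 (adjusted exact p = 0.000956). Hox genes lie side by side in 4 clusters, while both tests count them as independent genes, so these p-values can be too small. Of 16 Hox genes of groups 1 to 6, which act further forward, 13 had a peak in both (adjusted exact p = 0.502), among the strongest Hoxa4 (5.71 and 4.16) and Hoxb4 (4.31 and 3.43), with none at Hoxb3 and Hoxd3. The difference of their share from other genes turned from 11.5 percentage points to -6.28 among the strongest 50% of peaks and -22.4 in the FDR 0.001 lists, where that of groups 9 to 13 was -50.1 and -47.4. The 2 groups were not tested against each other.

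Genes of cell state were accessible throughout. All 16 housekeeping promoters had a peak in both animals (adjusted p = 0.0223, Fisher's exact test), led by Rplp0 (22.5 and 25.5), Ywhaz (22.9 and 21.2) and Tbp (20.2 and 17.3). So did all 14 circadian clock promoters (adjusted exact p = 0.0305), led by Per1 (38.7 and 34.2), Nr1d1 (31.9 and 33.5) and Nr1d2 (29.7 and 33.7), and so did all 12 immediate early and stress promoters (adjusted exact p = 0.0478), led by Jun (43.7 and 32.6), Atf3 (26.1 and 28.1) and Dusp1 (17.2 and 18.0). Genes of like CpG content were accessible in 87.5%, 92.9% and 83.3% (adjusted permutation p = 0.277, 0.540 and 0.442). With every promoter accessible these lists could go no higher, so this test could not set them apart. Outside the tests listed above, their median promoter values were 17.1, 19.0 and 14.6, against 6.90, 7.20 and 6.45 for CpG-matched lists. Promoters without a peak counted as 0. These medians stood at percentiles 99.97, 100 and 99.31 of the matched lists. The adjusted permutation p was 0.00987, 0.00370 and 0.0863, so immediate early genes missed the threshold of 0.05. All 10 interferon response promoters tested had a peak in both animals, among the strongest Usp18 (11.9 and 10.2) and Irf7 (4.33 and 2.96). This list missed the threshold in Fisher's exact test (adjusted p = 0.0726) and exceeded CpG-matched lists, whose median was 50% (adjusted p = 0.00444). The 4 protein-coding genes of X inactivation and escape also all had one (adjusted exact p = 0.411), at Kdm6a (34.3 and 40), Kdm5c (20.9 and 23.5), Ddx3x (8.22 and 10.7) and Eif2s3x (8.15 and 5.42). So did the noncoding Xist (4.30 and 2.02) and Jpx (3.07 and 2.39), which were not tested.

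Across the 37 lists, 8 exceeded other genes in promoter peaks and 10 fell below them. In replicate 1 alone the 10 became 3 (hepatocyte, pancreas and posterior Hox) and the 8 became 0 by Fisher's exact test, with 9 lists above at an unadjusted p under 0.05. The shares of the 8 were unchanged there, at 95.8% for endothelial genes and 100% for the others. All protein-coding genes stood at 72.5%, against 69.8% in both animals. The adjusted exact p was then 0.0509 for lung epithelial transcription factors, endothelial, housekeeping and photoreceptor genes, and 0.0521 for alveolar type 2, clock and intestine genes. It was 0.0733 for alveolar type 1 and kidney, 0.0983 for club, immediate early and skeletal muscle, 0.145 for erythroid and 0.206 for natural killer and male germ cell genes. In replicate 2 alone, club, immediate early (adjusted exact p = 0.0514 for both) and photoreceptor genes (adjusted exact p = 0.136) lost their calls. A window of 2500 bp left 8 calls and ended those of alveolar type 1 and 2 and clock genes (adjusted exact p = 0.0870), hepatocyte (0.0977), club and immediate early (0.110), photoreceptor (0.293), skeletal muscle (0.414), male germ cell (0.453) and kidney genes (0.633). The strongest 50% of peaks ended those of alveolar type 1 (adjusted exact p = 0.0822), skeletal muscle (0.163) and club genes (0.602), and the FDR 0.001 lists those of photoreceptor (0.0731), intestine (0.0974) and club genes (0.416). Lists that gained a call below other genes were neutrophil genes, with the strongest 50% of peaks (-42.6 percentage points, against -29.8; adjusted exact p = 0.0180) and in the FDR 0.001 lists (-46.1; 0.0130), mesothelial genes with the strongest 50% (-62.5, against -3.12; 0.00787) and neuronal genes with 500 bp (-30.4, against -7.29; 0.0306). Interferon response genes gained one above in the FDR 0.001 lists (0.0431). CpG-matched lists were not drawn for these alternatives. At the main setting neutrophil genes stood at 40% against a CpG-matched median of 30%, mesothelial genes at 66.7% against 50% and neuronal genes at 62.5% against 75%. The neutrophil list was thus not below genes of like CpG content there.

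**Figure D2:**
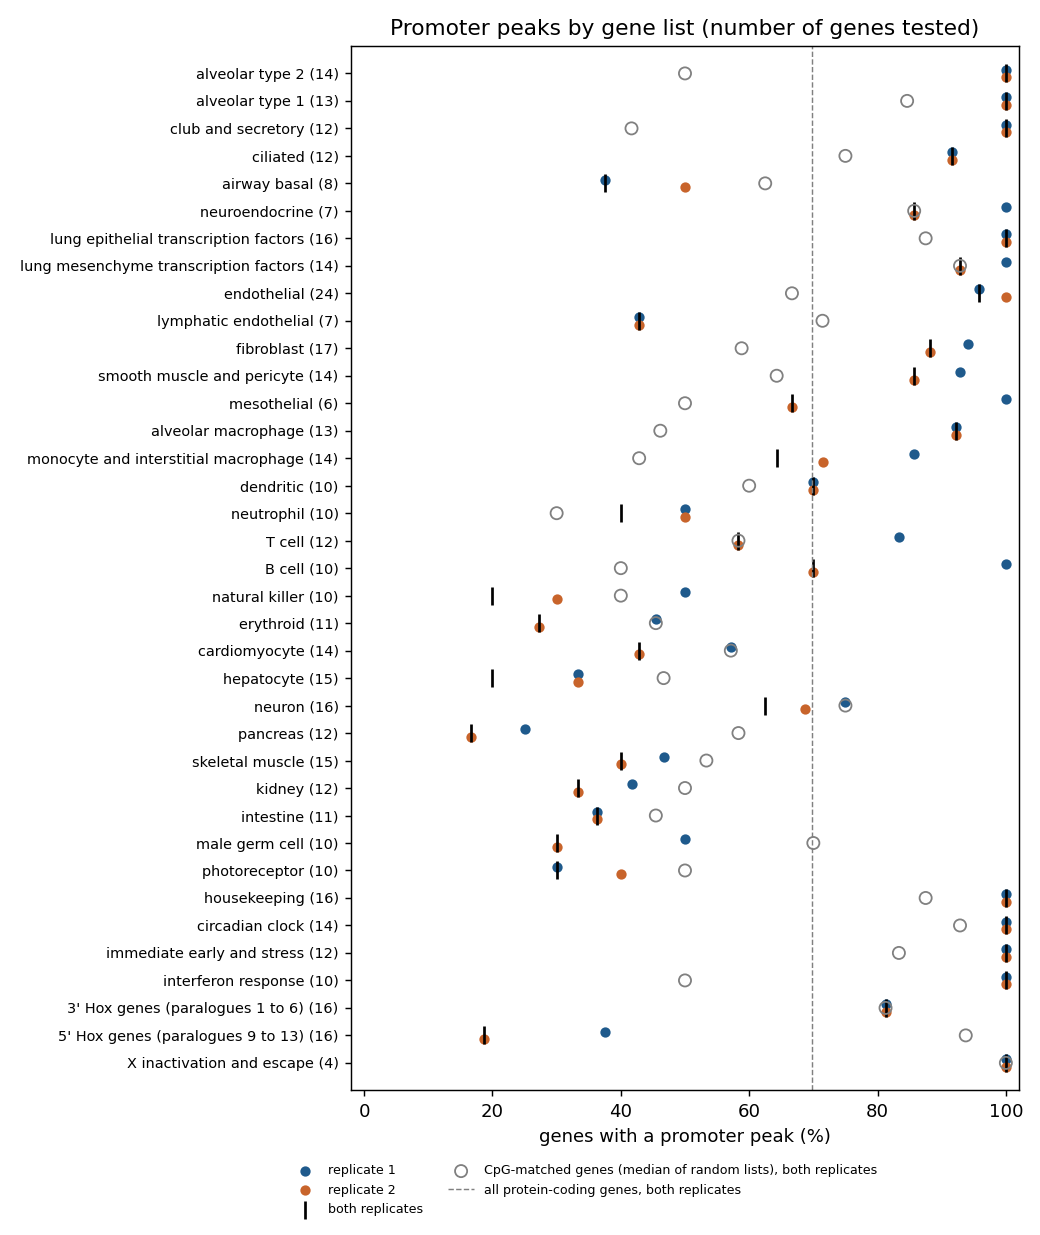
Percent of each list's genes with a promoter peak in replicate 1, in replicate 2 and in both, with the median of 10000 CpG-matched lists (open circles) and the level of all protein-coding genes in both replicates (69.8%, dashed line); the number of genes tested stands beside each list. Alveolar type 2 genes stand at 100% against a matched 50%, and posterior Hox genes at 18.8% against 93.8%.

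Counts of peaks around genes set 7 lists apart from matched genes. Promoter peaks had set 8 apart from CpG-matched lists, and 18 apart from other genes by Fisher's exact test. Alveolar type 2 loci held a median of 2.59 peaks per 10 kb, against 1.07 for matched genes (adjusted p = 0.00370, permutation test with random lists), endothelial loci 2.37 against 1.23 (adjusted p = 0.00247), and loci of lung epithelial transcription factors 3.03 against 1.88 (adjusted p = 0.0307). Clock loci (3.34 against 1.5) and immediate early loci (4.51 against 1.91) were higher still (adjusted permutation p = 0.00247 for both). Loci of neuronal genes (0.616 against 1.25; adjusted permutation p = 0.0307) and of posterior Hox genes (0.900 against 2.18; adjusted permutation p = 0.00592) held fewer. Neighbouring Hox loci overlap and share peaks, which the test does not allow for. Sftpc, the gene of surfactant protein C, named here after its values were seen, had 9.08 and 7.35 peaks per 10 kb in replicates 1 and 2, and Sftpb 8.74 and 6.72.

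The other 30 lists did not pass this test. Medians per 10 kb with those of matched genes were 2.06 and 1.45 for alveolar type 1, 1.85 and 0.914 for club, 2.15 and 1.2 for ciliated, 1.29 and 1.49 for basal and 1.44 and 2.04 for neuroendocrine genes. They were 2.2 and 1.59 for mesenchymal transcription factors, 0.550 and 1.15 for lymphatic endothelial, 1.72 and 1.01 for fibroblast, 2.06 and 1.26 for smooth muscle and pericyte and 1.22 and 1.06 for mesothelial genes. Among blood cells they were 1.44 and 0.964 for alveolar macrophage, 1.94 and 0.845 for monocyte and interstitial macrophage, 1.80 and 1.16 for dendritic, 1.33 and 0.582 for neutrophil, 1.16 and 1.11 for T cell, 1.25 and 0.779 for B cell, 0.697 and 0.643 for natural killer and 0.544 and 0.692 for erythroid genes. Other tissues gave 0.964 and 1.02 for cardiomyocyte, 0.755 and 1.14 for hepatocyte, 0.676 and 1.17 for pancreas, 0.685 and 1.06 for skeletal muscle, 0.757 and 1.11 for kidney, 0.847 and 0.969 for intestine, 1.22 and 1.37 for male germ cell and 0.738 and 1.06 for photoreceptor genes. Housekeeping loci gave 2.48 and 1.84, interferon response 1.87 and 0.944, anterior Hox 1.59 and 1.67, and X inactivation and escape 1.40 and 1.60. Some medians differed widely between replicates 1 and 2, among them lymphatic endothelial (0.963 and 0.355), B cell (1.85 and 0.767), pancreas (0.923 and 0.387) and erythroid loci (0.928 and 0.544). Replicate 1 also had more peaks in all. Among matched lists of the same replicate, lymphatic endothelial loci stood at percentiles 17.7 and 1.57, B cell at 96.75 and 62.3 and pancreas at 19.8 and 3.61. Erythroid loci stood at 57.8 and 53.8, close to each other.

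In replicate 2 alone alveolar type 2, endothelial (adjusted permutation p = 0.0748 for both) and lung epithelial transcription factor loci (0.0962) lost their calls, and in replicate 1 alone neuronal loci did (0.0871). The strongest 50% of peaks ended the calls of alveolar type 2, endothelial, lung epithelial transcription factor and posterior Hox loci (adjusted permutation p = 0.0536 for all 4). Without a flank, alveolar type 2 (adjusted permutation p = 0.0999), immediate early (0.192), neuronal (0.281) and lung epithelial transcription factor loci (0.352) lost theirs, and with 50000 bp endothelial loci did (0.114). Calls above matched genes were gained by alveolar type 1 loci with 50000 bp (adjusted permutation p = 0.0391) and outside promoters (0.0111), ciliated loci outside promoters (0.0465), smooth muscle and monocyte loci in replicate 1 alone (0.0462 for both), alveolar macrophage loci without a flank (0.0370) and housekeeping loci in the FDR 0.001 lists (0.0287). Lymphatic endothelial loci gained one below with 50000 bp (adjusted permutation p = 0.0388) and in the FDR 0.001 lists (0.0452). Clock loci kept theirs under all alternatives. With peaks outside promoters alone the posterior Hox (adjusted permutation p = 0.856) and neuronal differences (0.591) were lost. With a flank of 50000 bp the lung epithelial transcription factors lay 0.0138 peaks per 10 kb below matched genes (adjusted permutation p = 0.982).

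**Figure D3:**
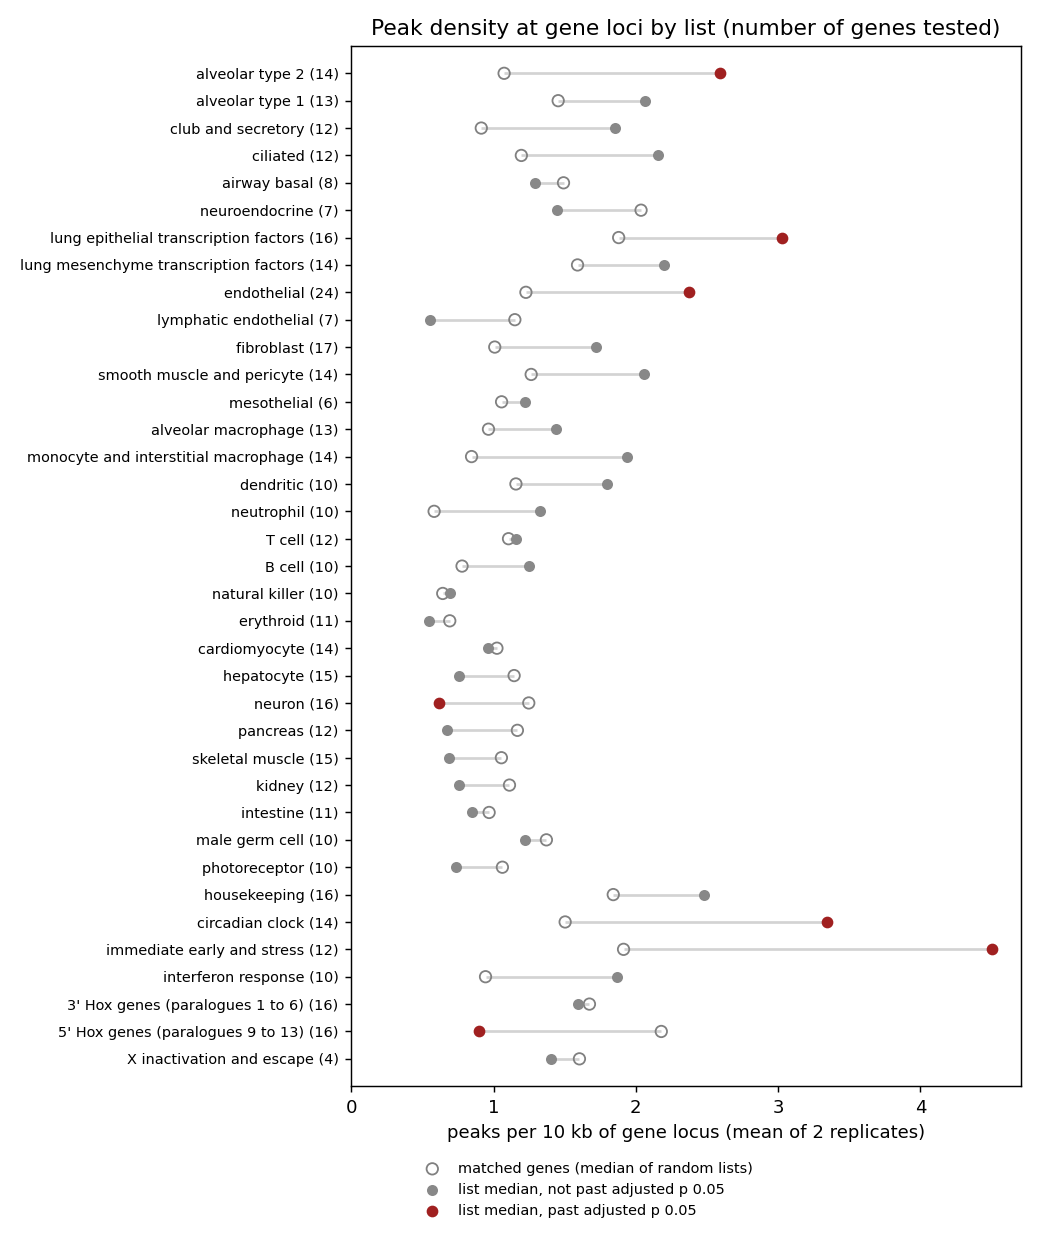
Median peaks per 10 kb of gene locus for each list, as the mean of both replicates (filled points, red where the adjusted p is under 0.05), with the median of 10000 matched random lists (open circles). Immediate early loci lie farthest to the right, at 4.51 against 1.91, and posterior Hox loci lie at 0.900 against 2.18.

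Over all protein-coding loci of 30000 bp or more, Midn on chromosome 10 (80148272 to 80158368) was the densest, with 9.97 ± 0.940 peaks per 10 kb (SD, n = 2). It was followed by the histone demethylase Kdm6b (7.54 ± 0.603), Inpp5k (6.73 ± 0.187), Bcl9l (6.72 ± 1.73), Rassf1 (6.67 ± 0.691), Smad7, an inhibitor of TGF-β signalling (6.61 ± 3.21), Hnrnpl (6.52 ± 0.419), Rhof (6.45 ± 1.14), Gnai2 (6.43 ± 1.89) and Lzts2 (6.42 ± 0). The longest unbroken regions under FDR 0.05 in replicate 1 were 7409 bp over Zfp503, 5450 bp over noncoding genes 1622 bp from Setd1b, 5345 bp over Ccn1, 5153 bp over Sin3a and 4988 bp over the noncoding Neat1. In replicate 2 they were 6085 bp over Sin3a, 5730 bp over Marcks, 4818 bp over Tns2, 4554 bp over Zfp503 and 4224 bp over Jun.

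The sequence of CTCF, the insulator-binding protein, had the highest mean ratio over flanking windows. It occurred in 3.58% ± 0.312 of peaks (SD, n = 2), 59.7 ± 4.06 times as often as in flanking windows, where its shuffled versions gave 5.36. Next came the sequences of the neuronal repressor REST (49.7 ± 17.7), SP/KLF (17.1 ± 2.28), NRF1 (15.3 ± 1.85), the myeloid factor PU.1 (11.3 ± 5.70), NFI (10.5 ± 3.68), YY1 (6.52 ± 1.94) and CpG-containing ETS sites (6.37 ± 0.517). Shuffled versions gave 3.04 for REST, 6.10 for SP/KLF, 6.46 for NRF1 (up to 21.1 in replicate 2, above the 16.6 of NRF1 itself), 0.728 for PU.1, 1.76 for NFI, 1.14 for YY1 and 1.43 for ETS. Relative to its shuffled versions, REST (16.3) and PU.1 (15.6) stood above CTCF (11.1). Shuffling does not keep neighbouring bases together, and the shuffled CTCF sequences gained CpG, so this order depends on the shuffles. Against GC-matched windows CTCF (41.8) stood above REST (16.6) and PU.1 (7.86 ± 4.28). REST, PU.1 and NFI sequences were rare, in 0.120%, 0.0970% and 0.121% of peaks, and their ratios rested on few flanking windows (8, 27 and 39 of 392532 in replicate 1). Among factors with roles in lung cells, AP-1 sequences were in 7.23% ± 0.290 of peaks (2.17 ± 0.0930 times), TEAD in 5.70% ± 0.0770 (1.77 ± 0.0215), NKX2-1 in 1.88% ± 0.108 (1.77 ± 0.0928, shuffled 1.44), CEBP in 0.562% ± 0.0212 (5.58 ± 0.109), GRHL in 0.133% ± 0.00832 (3.51 ± 0.426) and FOX in 6.54% ± 0.132 (1.10 ± 0.00762), all of these named after their values were seen. The lung lists also held GATA, SOX and TBX genes, whose sequences did not stand out in this way. GATA stood at 1.02 ± 0.00154 and SOX at 1.00 ± 0.0172, and TBX lay below its flanks. The lowest ratios were those of OCT (0.803 ± 0.0154), TBX (0.790 ± 0.00790) and CRX (0.780 ± 0.0210).

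In all, 31 of the 37 sequences were above and 4 below their flanks in both animals. Peaks were richer in GC than their flanks, 51.1% against 44.6% in replicate 1 and 52.4% against 44.9% in replicate 2. Against GC-matched windows, CTCF stood at 41.8, REST at 16.6, SP/KLF at 5.75, NRF1 at 8.23, YY1 at 3.31, CEBP at 8.78, GRHL at 1.80 and FOX at 1.93. OCT turned to 1.11 and CArG from 0.967 to 1.12, and NF-kB, above its flanks at 1.49, turned to 0.887, with shuffled versions at 3.04 over the flanks. Outside promoters SP/KLF stood at 6.56, NRF1 at 4.34, YY1 at 1.38 and ETS sites with CpG at 3.39.

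Footprints were short, with medians of 11 and 10 bp. Replicate 1 had 522527 and replicate 2 had 353617, and 88.4% and 88.9% lay in that animal's peaks. Of the peaks, 80.7% and 75.6% held at least 1 footprint, from 23.4% and 15.2% of the weakest 10% to 100% of the strongest 10% in both. Footprints were shared less than peaks: 42.9% of those of replicate 1 and 67.7% of those of replicate 2 overlapped one of the other animal by 1 bp or more. Placed at random within their own peaks, 29.6% and 43.9% would overlap, against 42.8% and 67.8% of the called footprints in peaks. With a reciprocal overlap of 50% the shares were 30.5% and 45.1%.

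The sequence of NRF1, an activator of mitochondrial genes that binds CpG-rich promoters, had the highest mean ratio in footprints. NRF1 sequences were 76.9 ± 20.1 times (SD, n = 2) as frequent in footprints as in random windows of the same animal's peaks, CTCF 37.6 ± 15.2, RFX 22.1 ± 3.39, SP/KLF 21.4 ± 2.29, CRE 14.8 ± 2.71, REST 14.7 ± 11.7, NFI 12.5 ± 8.79 and YY1 9.15 ± 2.14. Strong peaks held footprints more often and lay more often at promoters. The ratios therefore mix differences between peaks with placement within peaks. These ratios rest on few random windows with the sequence: 5 and 7 in replicates 1 and 2 for NRF1, 7 and 4 for RFX, 8 and 13 for REST and 10 and 16 for NFI. With a flank of 10 bp RFX (12.3) fell below SP/KLF (14.3), whose shuffled versions gave 7.28 at 5 bp. HNF1 sequences were too rare for a ratio. Of NRF1 sites in peaks, 94.7% in replicate 1 and 93.0% in replicate 2 lay in a footprint, and of CTCF sites 90.6% and 81.8%. AP-1 sites were footprinted far less often, in 23.9% and 20.8%, against 18.0% for its shuffled versions. Shares of sites were taken over all peaks and not compared at like peak strength. At the other end, GATA (0.544 ± 0.0718), FOX (0.406 ± 0.0296) and glucocorticoid receptor sequences (GRE; 0.343 ± 0.00744) were less frequent in footprints than in random windows. With flanks of 10 and 0 bp the ratios were 0.629 and 0.325 for GATA, 0.629 and 0.143 for FOX and 0.566 and 0.101 for GRE. Shuffled GATA was as low (0.530), shuffled FOX gave 0.573 and shuffled GRE 1.42. For GATA 12.1% of sites were footprinted in both animals, against 10.8% of shuffled sites, and 7.92% and 5.26% of GRE sites were footprinted, against 14.2% for its shuffled versions. Of the sequences with a ratio, 22 were above and 11 below the random windows in both animals. Footprints were richer in GC (58.8% and 59.7%) than the random windows (50.4% and 52.1%), and the NRF1 ratio ran from 38 with a flank of 10 bp to 311 with none.

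**Figure D4:**
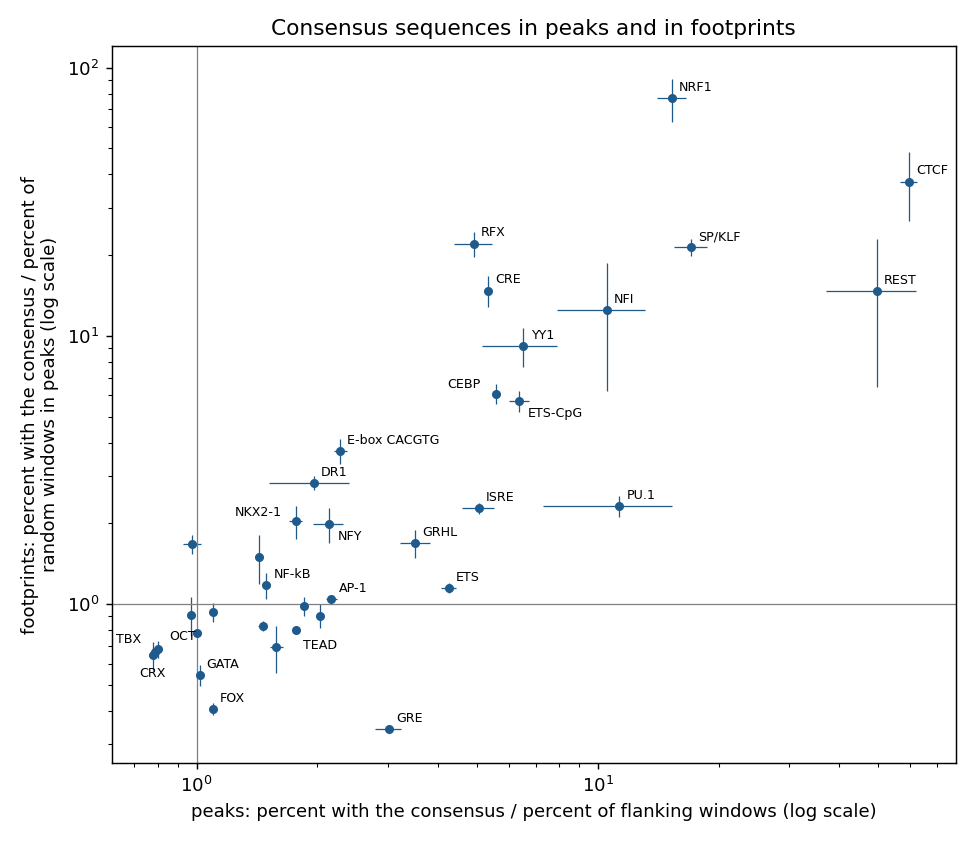
Ratio of consensus sequences in peaks over flanking windows (horizontal, log scale) against their ratio in footprints over random windows within peaks (vertical, log scale); points are means of 2 replicates and bars run to the value of each replicate. CTCF lies at 59.7 and 37.6, NRF1 at 15.3 and 76.9 and GRE at 3.01 and 0.343; HNF1 has no vertical value and is left out.

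The X chromosome held far fewer peaks than any autosome. It had 34.5 peaks per Mb in replicate 1 and 24.3 in replicate 2, which is 0.379 ± 0.0148 (SD, n = 2) of the autosomes together. The sparsest autosome, chromosome 14, had 70.1 and 50.7 per Mb, and the densest, chromosome 11, had 126 and 95.5. The Y chromosome, absent from females, carried 46 and 26 peaks, or 0.522 and 0.295 per Mb. Among the strongest 50% of peaks the X stood lower, at 0.252 of the autosomes.

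**Figure D5:**
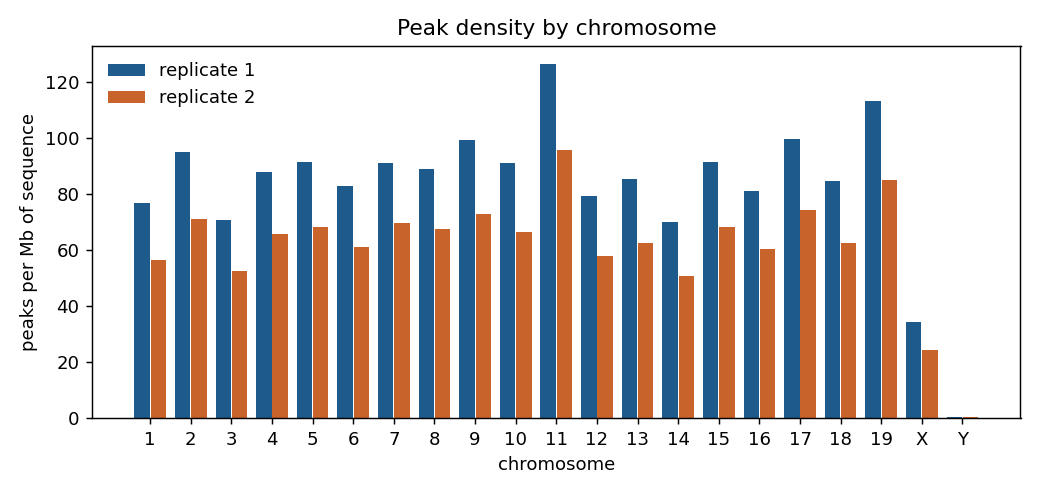
Peaks per Mb of sequence on each chromosome in replicate 1 and replicate 2. The X chromosome stands at 34.5 and 24.3, below every autosome in both replicates, and chromosome 11 is the highest at 126 and 95.5.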

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

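The alternative with the authors' FDR 0.001 lists was chosen only after the data had been seen; the others were set before. No paired analysis was possible because the series held 1 group. The cause of a change was not tested unless stated. Shared peaks were 59.8% of replicate 1 and 80.6% of replicate 2 with a reciprocal overlap of 50%, 80.9% and 80.8% with equal numbers of peaks, 69.6% and 92.7% at FDR 0.005, 69.1% and 93.0% in the FDR 0.001 lists, and 51.1% and 77.7% for merged regions under FDR 0.05. Promoter, exon, intron and intergenic shares were 14.8%, 4.62%, 40.8% and 39.8% with a window of 500 bp, 27.6%, 2.74%, 32.8% and 36.8% with 2500 bp (by construction, since the window takes bases from the other classes), 27.7%, 3.62%, 35% and 33.6% for the strongest 50% of peaks, and 24.0%, 3.56%, 35.4% and 37.1% in the FDR 0.001 lists. With 1 replicate left out they ran from 18.8% to 21.2%, 3.75% to 3.77%, 36.8% to 38.5% and 38.2% to 38.9%.

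For promoters, 8 lists lay above and 10 below other genes. With a window of 2500 bp there were 3 and 5, and against CpG-matched lists 6 and 2. Leaving out 1 replicate gave 0 to 6 above and 3 to 9 below; without replicate 2, Fisher's exact test called 0 above, with 9 at an unadjusted p under 0.05. All 18 called lists kept their direction under the 7 alternatives, and the hepatocyte, pancreas and posterior Hox lists kept their calls with either replicate left out. Over all lists and alternatives, 204 outcomes stayed on their side of the threshold, 47 lost a call and 8 gained one; 22 changes of direction concerned lists without a call. For loci, 5 lists lay above and 2 below matched genes. There were 3 and 1 without a flank, 2 and 1 with the strongest 50% of peaks, and with peaks outside promoters 7 above and 0 below (permutation test; 12 and 0 at an unadjusted p under 0.05). Leaving out 1 replicate gave 2 to 7 above and 1 to 2 below. The lung epithelial transcription factors turned to -0.0138 peaks per 10 kb against matched genes with a flank of 50000 bp; 234 outcomes stayed, 15 lost a call and 9 gained one, and 28 changes of direction concerned lists without a call.

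Consensus sequences below the background in footprints numbered 11, and 17 without a flank; with 1 replicate left out, 12 to 13 were below and 23 to 24 above, and in peaks 4 to 6 below and 31 to 33 above. Shared footprints were 30.5% and 45.1% with a reciprocal overlap of 50%, and 51.3% and 69.3% within shared peaks. The X stood at 0.343 of the autosomes in the FDR 0.001 lists and 0.252 among the strongest 50%, and at 0.369 to 0.389 with 1 replicate left out. Of the weakest 10% of peaks, 16.9% in replicate 1 and 55.6% in replicate 2 were shared; depth as the cause was not tested.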

Other observations

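Of the tests below, that of single Hox clusters and that of a lymphoid share were chosen only after the result was seen. The strongest peaks of each animal, chosen after their values were seen, lay mostly at promoters. In both animals the first was the start of Dynlt1b on chromosome 17 (6430001 to 6430180; 82.3 in replicate 1 and 70 in replicate 2) and the next that of Gm21887 on the X chromosome (63.1 and 62.7). In replicate 1 a site on the X chromosome 35450 bp from Pak3 (60.5), Rab11b (53.0) and Dnpep (52.2) followed, and in replicate 2 Hjurp (52.8), Dnpep (52.7) and a site 7 bp from the nuclear receptor gene Esrra (43.4). Peaks in duplicated sequence were not filtered out here. Whether any of these values sums over several copies was not tested.

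The X chromosome held fewer peaks per Mb than any autosome in both animals. A lower number of genes was argued against as the whole cause: peaks per protein-coding gene stood at 0.567 of the autosomes, with 5.95 and 4.18 on the X against 6.39 and 4.89 on chromosome 7, the lowest autosome. Repeats were argued against likewise, since outside repeat-masked sequence the X stood at 0.451. A lower value per peak may leave more X sites under the calling threshold: X promoters with a peak had 0.632 of the median value of autosomal promoters of like CpG content, and fewer X genes had one (54.7% against 68.8% in replicate 1 and 51.3% against 66.1% in replicate 2). Allele-specific reads were not used here and no biological explanation was tested.

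Posterior Hox promoters held peaks less often than promoters of like CpG content. The contrast with anterior genes was not confined to a single cluster: at FDR 0.05 in 4 of 4 clusters a lower share of posterior than of anterior genes had a peak in both animals (Hoxa 1 of 4 against 5 of 5, Hoxb 0 of 2 against 4 of 5, Hoxc 2 of 5 against 3 of 3, Hoxd 0 of 5 against 1 of 3). Each cluster holds few genes, and the comparison with promoters of like CpG content was not repeated without each cluster. Peaks that just missed the calling threshold cannot be told apart from absent ones: 4 of 16 promoters overlapped a region under FDR 0.05 without a peak in both animals and 9 overlapped none in either, but the false discovery rates used here end at 0.05, so sites just past it are not seen. No biological explanation was tested.

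Promoters of B, T and natural killer cell genes had a peak in replicate 1 alone in 9 cases and in replicate 2 alone in 1. These lists were pooled because they showed this, so the greater number of peaks in replicate 1 cannot be told apart from other causes: with the same number of peaks the counts were 7 and 1 (percentile 100 of matched lists), but 1 and 1 for natural killer genes (54.2), and posterior Hox genes stood at 99.98. A larger share of lymphoid cells in replicate 1 cannot be told apart either: around these genes, peaks of replicate 1 alone minus those of replicate 2 alone stood at percentile 99.5 for B cell genes but 59.8 for T cell and 73.7 for natural killer genes, and at 100 for endothelial genes. With both animals in 1 group, no biological explanation beyond that share was tested.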
